A study of Mus musculus with 2 samples.

How the data were processed

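The series holds ATAC-seq peak lists of 2 biological replicates of mouse embryonic intestine at embryonic day 15.5, from pools of 78 and 62 embryos. Per the labels, DNA was fragmented by Nextera tagmentation with fragments of 200 to 750 bp, and the assembly is mm10. The aligner, the peak caller and the read depth are not given in the sources used here. Nothing states whether reads were shifted for the enzyme's cut.

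For each replicate the authors deposited peaks thresholded on the irreproducible discovery rate (IDR), a looser list of pseudoreplicated peaks and a ranked list. For both replicates together they deposited a conservative IDR list, an IDR list, a replicated list and a pseudoreplicated list, each derived from the alignments of both replicates. Per the file headers and the deposited description, the thresholded, pseudoreplicated, replicated and conservative lists were derived from alignments and 1 further file that is not described, and the ranked lists from alignments alone. The deposited score column is capped at 1000 and does not fall below 540 in the thresholded lists, the whole part of the score of an IDR of 0.05. The signal column holds the authors' own value per peak, relative to a background that is not stated. It was used to describe, rank or filter peaks within a list and to compare ranks of shared regions between the replicates. It also served in a permutation test of median signal between distal regions near epithelial and near mesenchymal genes. The −log10 columns hold −log10 p and q values per peak as deposited. The summit offset column was taken as deposited. The pair of ranked lists of the whole series was not used, because nothing states which replicate their columns hold.

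Overlapping peaks of a list were merged to regions, each placed at its summit of highest signal. The chromosome lengths of GRCm38.p6 fit the files, with 0 of 430090 peaks past a chromosome end. Genes and transcription start sites were taken from GENCODE M21, with 21938 protein-coding genes, 13374 lncRNA genes and 111646 TSS positions on 21 chromosomes. A region counted as found in the other replicate when the overlap covered at least 50% of either region. Chance was set by 100 seeded circular shifts along each chromosome. A summit within 1000 bp of a TSS was a promoter summit, and otherwise exon, intron or intergenic in that order. A promoter was accessible when a region lay within 1000 bp of any TSS of the gene. A distal region had its summit over 1000 bp from every TSS, so its edge could lie nearer. It was assigned to the nearest protein-coding TSS within 100 kb.

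The 27 gene lists (13 of cell types of the gut, 10 of other tissues, 3 of Hox genes and 1 of ribosomal proteins) and 20 motifs were fixed before the data were examined, as were the tests and the rule for named genes. All members matched a gene except Ahsp in the erythroid list and Cblif in the stomach list, whose older symbol Gif matched. Hnf4a is in the lists of epithelial regulators and liver, Tal1 in endothelium and erythroid, Krt19 in junctions and mesothelium, and Hoxb5 in the enteric nervous system and Hox groups 5 to 9. Promoters of a list were compared with all other protein-coding genes by a two-sided Fisher's exact test. Distal regions per gene were compared by a two-sided permutation test with 10000 random lists, drawn with replacement within 20 bins of territory length, the bases nearest to the gene and within 100 kb. The smallest p these draws can give is 0.0002 before adjustment. Gut lists and lists of other tissues were compared by 100000 permutations of their labels. Motifs were consensus strings on either strand with no mismatch (for example AGATAAG for GATA, TGASTCA for AP-1, CAAAGKYCA for HNF4 and GYMATAAA for CDX). Their share within 50 bp of distal summits was compared with windows centred 500 bp away by an exact McNemar test. Regions near genes of 4 epithelial lists and of 2 mesenchymal lists, and shares of regions found in the other replicate, were compared by Fisher's exact test. Each family was adjusted by Benjamini-Hochberg, and a call needed an adjusted p under 0.05 in both replicates, except that the share found in the other replicate was tested in each. Genes and regions are the units of these tests, so the p values describe these libraries. With 1 group, no test between groups of samples was possible.

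Named genes were the 3 members of each gut list with most distal regions (ties by summed signal) and the first with fewest, the member of each other tissue's list with most, Hox genes with examples, and the 5 genes and the 5 distal and 5 promoter regions with the highest values. Counts of single genes were not scaled to territory. Cdx1, Cdx2, Gata4 and Lgr5 and the 9 erythroid genes open in 1 replicate were named after their values were seen.

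The overlap rule, the tests of gene lists, the motif tests and the test of shares found were run on simulated data with known answers. Other steps, such as rank agreement, annotation shares, circular shifts, sequence matches and the permutation test of signal, were not simulated. In lists of at least 15 of the 21938 protein-coding genes with distal regions raised 4-fold, 21 of 22 were called, against 5 of 22 raised 2-fold and 0 of 108 unchanged lists, so an excess near 2-fold can be missed. For promoters, 16 of 22 lists set to 95% open were called, 7 of 22 set to 30% and 0 of 108 set to the level of other genes. In both simulations the 2 replicates were drawn independently, while the real replicates share most regions. The 0 of 108 is thus not a rate of false calls for the data, and the shares called may differ there too. Of 10 motifs put into 3% of 15000 summits, 10 were called, and of the other 10, the 1 called was HOX, whose string occurs in an inserted motif. With 13 and 10 lists, a log2 shift of 1 passed in 15 of 20 simulated data sets, a shift of 2 in 20 and no shift in 2. A motif put into 30% of the epithelial summits among 240 regions was the 1 called, in 1 simulated data set and not under the rule of both replicates. In the data the largest share near epithelial genes was 12.3% (AP-1), and smaller differences were not simulated for this comparison. The list simulated with more regions found in the other replicate was the 1 called among 15000 regions. In the simulated overlap of 1979 regions, 78.4% were kept and 78.4% found.

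Alternatives were other overlap rules, equal numbers of regions, the p column for ranks, peaks not merged, looser (pseudoreplicated) and stricter lists (regions at or above the median signal), the conservative pooled list, leaving out each replicate, promoter windows of 500 and 2500 bp, assignment limits of 50000 and 500000 bp, other matching, motif windows of 25 and 100 bp and a reversed consensus. The conservative pooled list held 40438 regions, more than the 29522 and 29706 of the replicates. It is thus not a stricter setting, and its calls come from a single list, without the rule of both replicates. Sequence matches were found with BLAST 2.17.0. Work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9.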

Results

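Chromatin accessibility was profiled by ATAC-seq, which inserts sequencing adapters into open DNA with a transposase, in intestine from B6NCrl mouse embryos at embryonic day 15.5. There was 1 group with 2 biological replicates, each a pool of tissue from many embryos of both sexes. Replicate 1 pooled 78 embryos and replicate 2 pooled 62. The values are the authors' peak lists on the mouse assembly mm10. No list gave read counts, so the depth of the libraries is unknown and no counting interval could be set. Differences between gene groups were therefore judged within each replicate, and a call needed both.

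The first question was how far the pools gave the same regions. The authors' list of reproducible peaks held 75078 peaks in replicate 1 and 74870 in replicate 2. Many of these peaks shared the same interval and differed in their summit. Merging left 29522 and 29706 regions, the number of distinct intervals as deposited, a mean of 29614 ± 130 (SD, n = 2). Median region width was 898.5 ± 6.36 bp, and the regions covered 27.3 ± 0.0329 Mb, or 1.00% ± 0.00121 of the genome. Of the regions of replicate 1, 83.4% were found in replicate 2, and 82.9% the other way. After random circular shifts along each chromosome the means were 1.34% and 1.34%. Regions missing from the other replicate had lower signal values, with medians of 5.11 against 7.57 in replicate 1 and 5.41 against 7.97 in replicate 2. With the regions of replicate 1 split by signal into 10 bins of equal size, the share found rose from 57.2% in the lowest bin to 99.9% in the highest. Against the looser list of the other replicate, 98.4% of replicate 1 regions and 99.1% of replicate 2 regions were found. Across 24619 shared regions the signal values had a Spearman rho of 0.921 and a Pearson r of 0.918 on the log2 scale. Regions are not independent replicates, so no p was computed. The summits lay a median of 11 bp apart.

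**Figure D1:**
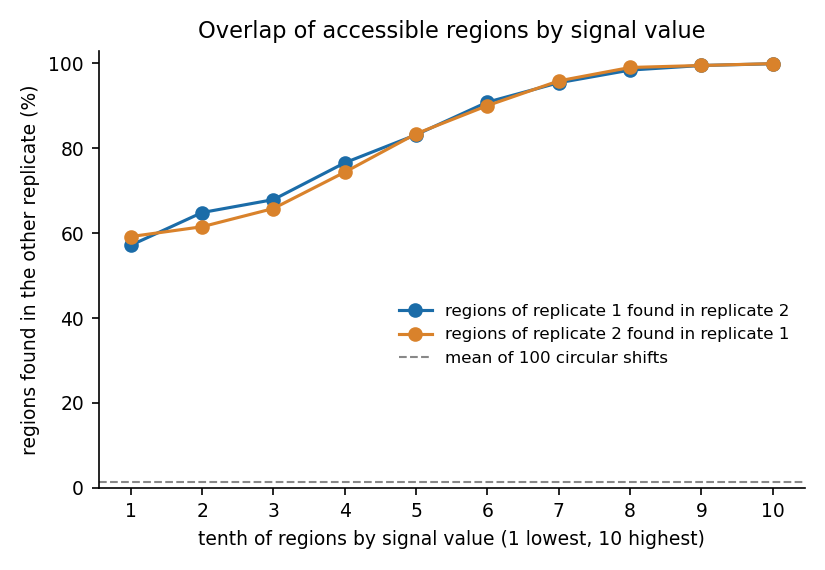
Share of regions of each replicate found in the other (vertical axis, percent) by bin of signal value from low to high (horizontal axis, 10 bins), with the mean of 100 circular shifts as a dashed line. In replicate 1 the share rises from 57.2% in the lowest bin to 99.9% in the highest.

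Promoters made up a large share of the open regions. Summits within 1000 bp of a transcription start site (TSS) of a protein-coding or lncRNA gene were 48.4% ± 0.0312 of regions (SD, n = 2), against 4.84% after circular shifts. That is 9.99 ± 0.0146 times the shifted share. Introns held 26.0% ± 0.143, intergenic sequence 23.1% ± 0.106 and exons 2.50% ± 0.0678, each below its shifted share of 39.1%, 52.8% and 3.25%. The shares have a common total, so the promoter excess by itself lowers those of the other classes. Shares among regions outside promoters were not computed, so depletion of introns or exons is not shown. Promoter regions were also wider, with a median of 1112 ± 12.02 bp against 696.5 ± 6.36 bp in introns. Their median signal value was 8.98 ± 0.219, against 6.04 ± 0.244 in introns. An accessible promoter was found for 13295 protein-coding genes (60.6%) in replicate 1 and 13361 (60.9%) in replicate 2, and for 12897 in both.

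**Figure D2:**
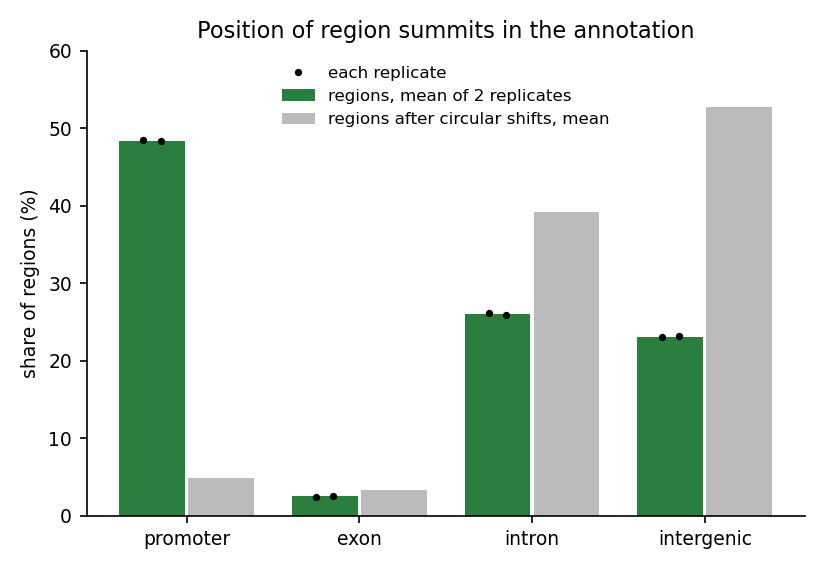
Share of region summits by annotation class (vertical axis, percent), as the mean of both replicates with each replicate as a point, beside the mean after circular shifts. Promoters hold 48.4% of summits and 4.84% of shifted summits.

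The 5 distal regions of highest signal in the conservative list of the series were narrow and intergenic. The highest, on chromosome X at 143482936 to 143483180, had a signal value of 54.3 and lay 35.5 kb upstream of Pak3. The next lay on chromosome 2 at 69355469 to 69355735 (49.0, 13 kb upstream of Abcb11). Another was on chromosome 5 at 60042765 to 60043140 (41.1), with the nearest coding TSS, that of G6pd2, 1766 kb away. The remaining ones were on chromosome 10 at 96077546 to 96077953 (40.9, 58.9 kb upstream of Gm5426) and on chromosome 2 at 3964425 to 3964690 (31.7, 53.2 kb upstream of Frmd4a). Those nearest to Abcb11, G6pd2 and Gm5426 matched mitochondrial DNA over 129, 336 and 352 bp. Of the 5 promoter regions of highest signal, those nearest to Zfp960, 6720489N17Rik and Gm49359 had signal values of 26.1, 25.3 and 24.0, and the sequence at their summits occurred at 6, 3 and 4 further places in the assembly. The promoter regions nearest to Gm13283 (27.4) and Zfp81 (22.9) had no such further place. The summit of the former lay 2.4 kb from the TSS of Gm13283, its nearest coding gene, so the TSS within 1000 bp was that of a lncRNA gene.

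Promoters of epithelial regulators, of epithelial junction and keratin genes, and of stem cell and Wnt target genes were accessible more often than those of other genes. Members with an accessible promoter were 23 of 24 epithelial regulators in each replicate (95.8% ± 0.00), which include the intestinal determinant Cdx2, Hnf4a and Gata4. The member without one in either replicate was Cdx1. Epithelial junction and keratin genes, such as Epcam and Krt8, reached 93.2% ± 3.21, and stem cell and Wnt target genes, such as Lgr5 and Rnf43, 88.9% ± 0.00. Among all other protein-coding genes the share was about 60.7%. These 3 lists passed Fisher's exact test in both replicates, with larger adjusted p values of 0.000832, 0.00846 and 0.0257. All 3 calls ended when only regions at or above the median signal were kept, where the shares were 52.1%, 36.4% and 50%, against a mean of 47.1% of other genes (larger exact adjusted p values of 0.907, 0.444 and 1.00). The 24 ribosomal protein genes, a control used by every cell, were all accessible (exact adjusted p = 0.000116).

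Promoters of leukocyte genes (17.5% ± 3.54) and enteric nervous system genes (31.25% ± 2.95) were accessible less often than those of other genes, with larger exact adjusted p values of 0.000926 and 0.0185. Promoters of 9 of the 10 lists of other tissues were also below other genes. They ranged from germ line (6.25% ± 0.00, exact adjusted p = 0.000116) over epidermis (12.5% ± 0.00), liver (15% ± 0.00), stomach (20% ± 0.00), heart (21.9% ± 4.42), skeletal muscle (23.5% ± 0.00), forebrain (25% ± 0.00) and lung (25% ± 0.00) to kidney and urogenital ridge (31.25% ± 0.00, exact adjusted p = 0.0328). Pancreas genes (39.5% ± 3.72) did not pass the test (exact adjusted p = 0.139). The other gut lists did not pass it either. They were smooth muscle at 72.5% ± 3.54, gut mesenchyme at 69.6% ± 2.53, interstitial cells of Cajal at 66.7% ± 0.00, mesothelium at 65.0% ± 7.07, absorptive enterocyte at 55.6% ± 5.24, endothelium at 50% ± 0.00, and secretory and enteroendocrine genes at 38.5% ± 5.44. With the looser lists the calls of enteric nervous system (83.3%), stomach, liver, lung, kidney, heart and forebrain genes ended, as did those of enteric nervous system, kidney and forebrain in the conservative pooled list, of lung, kidney, heart and forebrain with a promoter window of 2500 bp, of kidney with 500 bp and of lung in the higher-signal regions. Gut mesenchyme and smooth muscle passed as higher with the looser lists (96.4% and 95%, other genes 69.2%) and in the conservative pooled list (89.3% and 95%, other genes 64.7%), while gut mesenchyme (17.9%), absorptive enterocyte, secretory, endothelium, mesothelium and pancreas genes passed as lower in the higher-signal regions, and secretory genes in replicate 2 alone. The conservative pooled list held 40438 regions, more than the list of either replicate, so it is not a stricter setting.

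Of the erythroid promoters, 13 of 17 were accessible in replicate 1 (exact adjusted p = 0.297 against other genes) and 4 of 17 in replicate 2 (exact adjusted p = 0.00618, lower), so the mean of 50% ± 37.4 describes neither pool. The 9 open in replicate 1 only were the adult alpha and beta globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, and the red cell membrane genes Gypa, Slc4a1, Ank1, Epb42 and Spta1. No erythroid promoter was open in replicate 2 only. The globin pairs are near-identical copies, so reads may be shared between them and their values are uncertain. The exact McNemar test between the replicates, chosen after the values were seen, gave p = 0.00391 and an adjusted p of 0.105 over the 27 lists, which does not pass the threshold. With the looser lists 15 and 11 of the 17 were accessible. Leukocyte promoters were open for 4 of 20 genes in replicate 1 and 3 in replicate 2, and liver promoters for 3 of 20 in both.

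**Figure D3:**
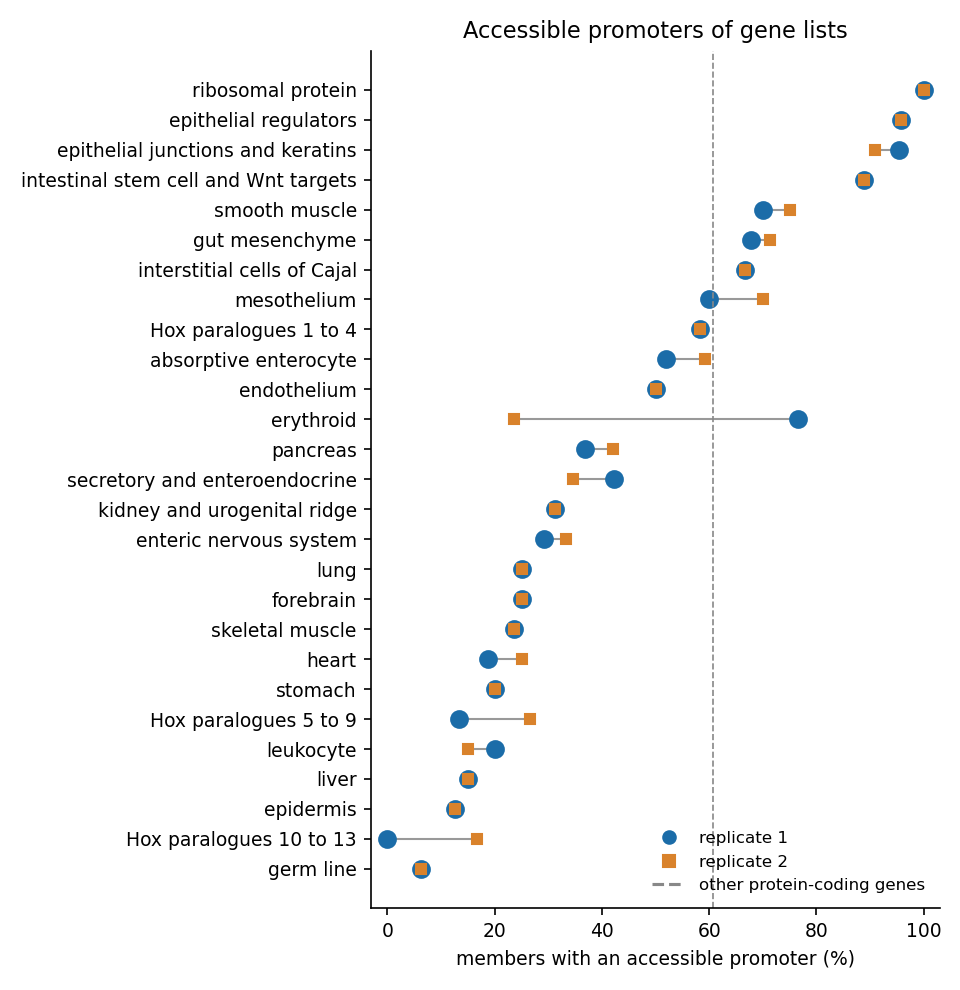
Members of each gene list with an accessible promoter (horizontal axis, percent) in replicate 1 (circles) and replicate 2 (squares), with the mean of other protein-coding genes as a dashed line. The erythroid list has 13 of 17 members open in replicate 1 and 4 in replicate 2.

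Distal regions, with their summits over 1000 bp from every TSS, numbered 15227 in replicate 1 and 15335 in replicate 2. Of these, 13266 and 13236 had their nearest coding TSS within 100 kb and were assigned to its gene. No such region was assigned to 68.7% and 69.0% of protein-coding genes. The question was which cell types of the gut the distal regions point to.

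The 3 lists called as having more distal regions than matched genes were epithelial. Epithelial regulators had 3.73 ± 0.0884 distal regions per gene (SD, n = 2) against 0.944 in genes matched on territory, a ratio of 3.95 ± 0.0372. Prdm1, a repressor that controls the timing of gut epithelial maturation, led with 8.5 ± 0.707 distal regions. Grhl2, a regulator of epithelial junctions, had 7.5 ± 0.707 and the nuclear receptor gene Nr5a2 had 7.0 ± 1.41, while Foxa3 had none. Epithelial junction and keratin genes had 1.91 ± 0.129 per gene against 0.429, a ratio of 4.46 ± 0.401. Their leading members were the adhesion genes Epcam (6.5 ± 0.707) and Cdh17 (6.0 ± 1.41) and the simple epithelial keratin Krt8 (3.5 ± 0.707), and the brush border cadherin gene Cdhr2 had none. Absorptive enterocyte genes had 1.80 ± 0.0262 per gene against 0.661, a ratio of 2.72 ± 0.0188. The brush border enzyme genes Mep1b (5.0 ± 1.41) and Dpp4 (4.5 ± 0.707) led this list with Cubn (4.5 ± 0.707), which had no accessible promoter, and the intestinal alkaline phosphatase gene Alpi had none. Counts of single genes were not scaled to territory. Territory was 266 kb for Prdm1 and 10.2 kb for Foxa3. For Epcam and Cdhr2 it was 113 and 27.9 kb, and for Mep1b and Alpi 136 and 17.5 kb. Each of the 3 lists had a permutation p of 0.0018 after adjustment in both replicates, which rests on the smallest p that 10000 draws can give. Among regions at or above the median signal the junction and keratin list was not called (ratio 1.97, permutation adjusted p = 1.00).

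Stem cell and Wnt target genes had 2.28 ± 0.157 distal regions per gene, 2.19 ± 0.130 times the matched mean, and passed in replicate 2 (permutation adjusted p = 0.0337) but not in replicate 1 (0.0634). They were called with looser lists, in the conservative pooled list and without matching. The crypt receptor gene Ephb2 had 7.5 ± 2.12, the Wnt feedback gene Rnf43 4.5 ± 0.707, Smoc2 4.0 ± 1.41 and Msi1 none. Secretory and enteroendocrine genes were near their matched mean (ratio 1.08 ± 0.202, permutation adjusted p = 1.00). Within this list the goblet cell gene Agr2 had 4.5 ± 0.707 distal regions, the secretory regulator Atoh1 3.5 ± 0.707, Dclk1 2.0 ± 1.41 and Arx none.

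The non-epithelial gut lists were not called. Gut mesenchyme had a ratio of 0.829 ± 0.141 and smooth muscle of 1.67 ± 0.1253, with larger permutation adjusted p values of 1.00 and 0.880. The Hedgehog effector Gli2 (3.0 ± 0.00), Nr2f2 (2.5 ± 0.707) and the collagen gene Col1a1 (2.5 ± 0.707) had the most regions among mesenchymal genes, and Bmp4 had none. In smooth muscle the tropomyosin gene Tpm1 had 7.0 ± 1.41, Csrp1 3.0 ± 1.41 and the myosin light chain kinase gene Mylk 3.0 ± 0.00. Actg2, which encodes enteric smooth muscle actin, had neither a distal region nor an accessible promoter. Ratios were 0.963 ± 0.135 for the enteric nervous system, 0.768 ± 0.0430 for interstitial cells of Cajal, 1.11 ± 0.0398 for endothelium, 0.807 ± 0.0666 for leukocytes, 1.254 ± 0.783 for erythroid genes and 0.749 ± 0.00651 for mesothelium, each with a larger permutation adjusted p of 1.00. The erythroid log2 ratio was 0.854 in replicate 1 and -0.515 in replicate 2, so its mean describes neither pool. Members with the most regions were the neural crest receptor gene Erbb3 (3.0 ± 0.00), the pacemaker channel gene Ano1 (4.0 ± 1.41), the lymphatic gene Lyve1 (4.0 ± 0.00), the macrophage receptor gene Mrc1 (2.0 ± 0.00), the embryonic globin gene Hbb-y (2.0 ± 1.41) and Upk1b (2.0 ± 1.41). The next in these lists were Ednrb (2.5 ± 0.707) and Hand2 (2.5 ± 0.707), Etv1 (2.0 ± 0.00) and Prkcq (0.5 ± 0.707), Cdh5 (3.0 ± 0.00) and Sox17 (2.0 ± 0.00), Runx1 (2.0 ± 0.00) and Spi1 (1.5 ± 0.707), Klf1 (1.0 ± 0.00) and Slc4a1 (1.0 ± 0.00), and Aldh1a2 (1.0 ± 0.00) and Lrrn4 (1.0 ± 0.00). The first members without any were Hoxb5, Gucy1a1, Emcn, Aif1, Epb42 and Gpm6a. Unadjusted, 4 gut lists had a permutation p under 0.05 in each replicate, the 3 called and stem cell and Wnt target genes.

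**Figure D4:**
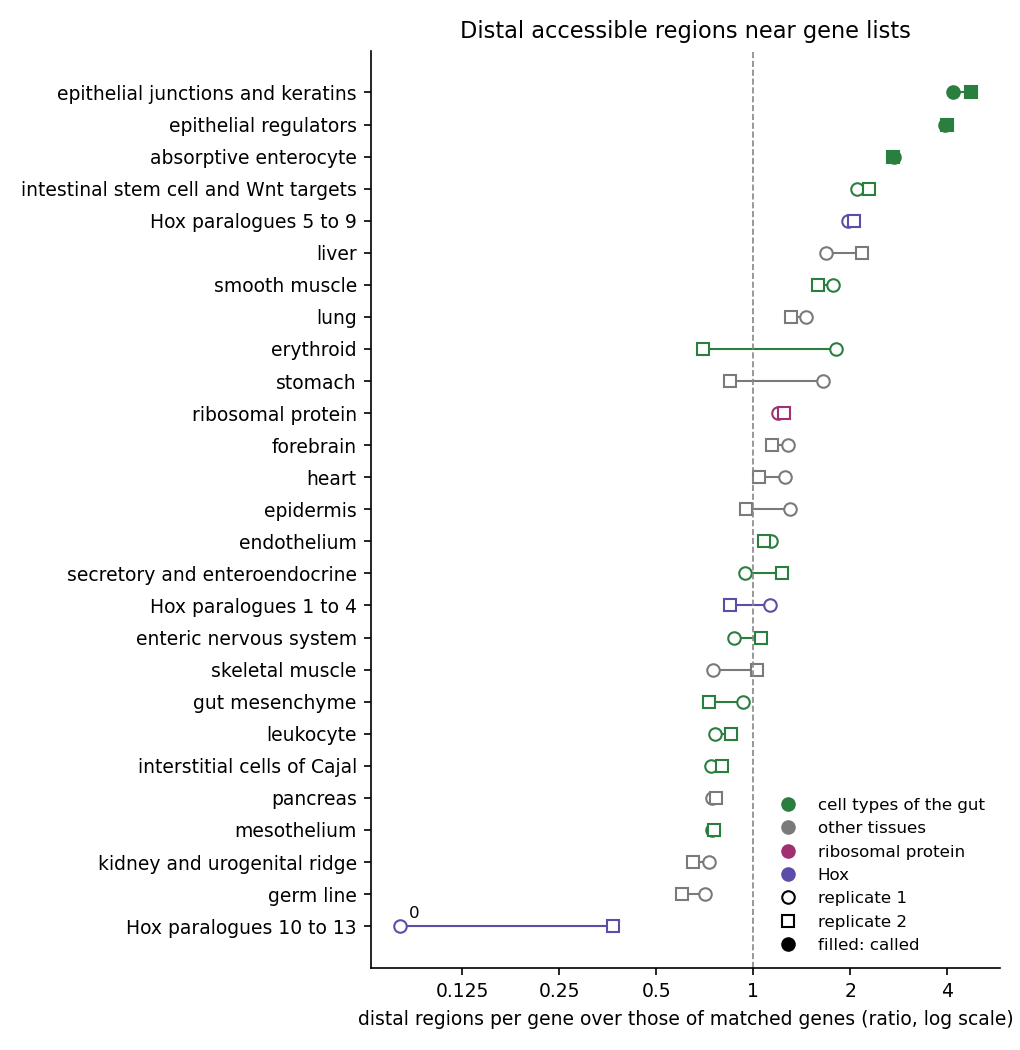
Distal regions per gene over those of matched genes for 27 gene lists (horizontal axis, ratio, log scale), in replicate 1 (circles) and replicate 2 (squares), with called lists filled. A ratio of 0 is drawn at the left edge and marked 0. The called lists lie at mean ratios of 2.72 to 4.46.

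No list of another tissue was called, and unadjusted 0 in replicate 1 and 1 in replicate 2, liver, had a permutation p under 0.05. Liver had the highest ratio among them, 1.93 ± 0.354 (larger permutation adjusted p = 0.659), and its leading member Hnf4a, with 4.5 ± 0.707 distal regions, is also in the list of epithelial regulators. The others ran from lung (1.38 ± 0.103), stomach (1.246 ± 0.562), forebrain (1.21 ± 0.0988), heart (1.15 ± 0.150) and epidermis (1.13 ± 0.252) to skeletal muscle (0.888 ± 0.196), pancreas (0.757 ± 0.0152), kidney and urogenital ridge (0.689 ± 0.0574) and germ line (0.656 ± 0.0758). Single genes of these lists still had several distal regions, among them Bcl11b (6.0 ± 0.00), Pax8 (4.5 ± 0.707), Irx4 (4.5 ± 0.707) and Scgb1a1 (3.5 ± 0.707). The leading members of the remaining lists, Muc6, Bhlha15, Ryr1, Dsg3 and Dazl, each had a mean of 2.0. Over lists, the 13 gut lists had a mean log2 ratio of 0.49 ± 0.91 (SD over lists) and the 10 lists of other tissues 0.05 ± 0.49. The difference of 0.44 did not pass a two-sided permutation test of the list labels (p = 0.181).

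Hox promoters of later paralogue groups were accessible less often than those of other genes. Groups 1 to 4, with anterior members such as Hoxa1 and Hoxb4 open in both replicates, had 58.3% ± 0.00 of promoters accessible. Groups 5 to 9 had 20% ± 9.43, among them Hoxb7 and Hoxc6 in both replicates, and groups 10 to 13 had 8.33% ± 11.8. Both later groups passed the test, with larger exact adjusted p values of 0.0231 and 0.00618, and groups 1 to 4 did not (exact adjusted p = 1.00), except as lower in the higher-signal regions (8.33%). No test compared the groups with each other. With the looser lists the later groups reached 73.3% and 75.0%, above other genes and without a call, and in the conservative pooled list the calls ended too. The control ribosomal protein genes had a distal ratio of 1.22 ± 0.0373, and Hox groups had 0.987 ± 0.196, 2.01 ± 0.0591 and 0.183 ± 0.259 in order, with no call.

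Over the whole genome the protein-coding genes with the most distal regions were Gse1 (15.5 ± 2.12), the phosphodiesterase gene Pde4d (14.5 ± 0.707), the forkhead gene Foxp1 (13 ± 2.83), Zfp608 (12.5 ± 0.707) and Vps13d (12 ± 0.00). These counts were not scaled to territory. Territory was 316 kb for Gse1, 1565 kb for Pde4d, 705 kb for Foxp1, 297 kb for Zfp608 and 270 kb for Vps13d. In the conservative list of the series the strongest distal region of Gse1 spanned 120275926 to 120277379 on chromosome 8, in an intron of Gse1 and of the overlapping Gm20388, with a signal value of 8.85. That of Prdm1 lay on chromosome 10 at 44529107 to 44529896 (intergenic, signal value 10.9). Its summit was 1011 bp upstream of the TSS, so the region reached into the promoter window. The strongest distal region of Epcam lay on chromosome 17 at 87627805 to 87628920 (intergenic, 7.6 kb upstream, 7.92). For Hnf4a it was an intronic region on chromosome 2 at 163552162 to 163553005 (8.19). For Cubn it was intronic on chromosome 2 at 13469714 to 13470631 (11.97), for Agr2 intergenic on chromosome 12 at 35981644 to 35982353 (10.1), and for Sox17 intergenic on chromosome 1 at 4571263 to 4572312 (11.3), 74.5 kb upstream of the gene.

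Most of the consensus motifs were more frequent at distal summits than beside them. Of 20 motifs, 16 were more frequent within 50 bp of the summit than in windows 500 bp away and 1 was less frequent, by an exact McNemar test that had to pass in both replicates. HNF4 sites were at 4.96% ± 0.279 of summits (SD, n = 2), 7.96 ± 0.767 times the flank, and CDX sites at 4.53% ± 0.227, 3.44 ± 0.177 times. GATA sites were at 5.70% ± 0.718, 4.18 ± 0.137 times the flank, and KLF sites at 2.71% ± 0.0552, 9.53 ± 0.00860 times. HNF1 sites were rare, at 0.376% ± 0.0620, and 24.5 ± 10.6 times the flank. The larger exact adjusted p values of these 5 motifs ran from 2.04e-129 to 4.86e-12. AP-1 sites (7.47% ± 0.0281, 4.62 ± 0.310 times) and E-box sites (10.4% ± 0.191, 2.07 ± 0.00474 times) were the most widespread of the called motifs, and sites of the architectural factor CTCF were at 2.17% ± 0.230 (23.9 ± 5.04 times). FOX, ETS, TEAD, SOX, NFI, TCF, MEIS and NFY sites were also called as higher, at 1.36 ± 0.0769 times (MEIS) to 13.5 ± 0.707 times (NFI). NFI sites were at 0.0883% of summits. The flank shares of NFI (0.00654%) and HNF1 (0.0163%) were so low that their ratios rest on very few windows. The homeobox core HOX was lower at summits (1.78% ± 0.120, 0.635 ± 0.0647 times, exact adjusted p = 4.69e-07). The smooth muscle SRF CArG motif (1.28 ± 0.0219 times), GLI (1.05 ± 0.212 times) and PHOX2 (0.05 ± 0.0707 times), a motif of enteric neurons, were not called, with larger exact adjusted p values of 0.152, 1.00 and 0.0694. Against the reversed consensus the HOX call ended (1.13 times), as did that of ETS (0.888 times). The calls of ETS and NFI also ended among the higher-signal regions, while CArG was called as higher with looser lists (1.34 times), in the conservative pooled list and against the reversed consensus. PHOX2 was called as lower with looser lists, in the conservative pooled list, in replicate 2 alone and with a window of 100 bp. Its sites were at 0.00326% of summits and 0.0490% of flanks in the main setting, so its ratio there also rests on very few windows.

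**Figure D5:**
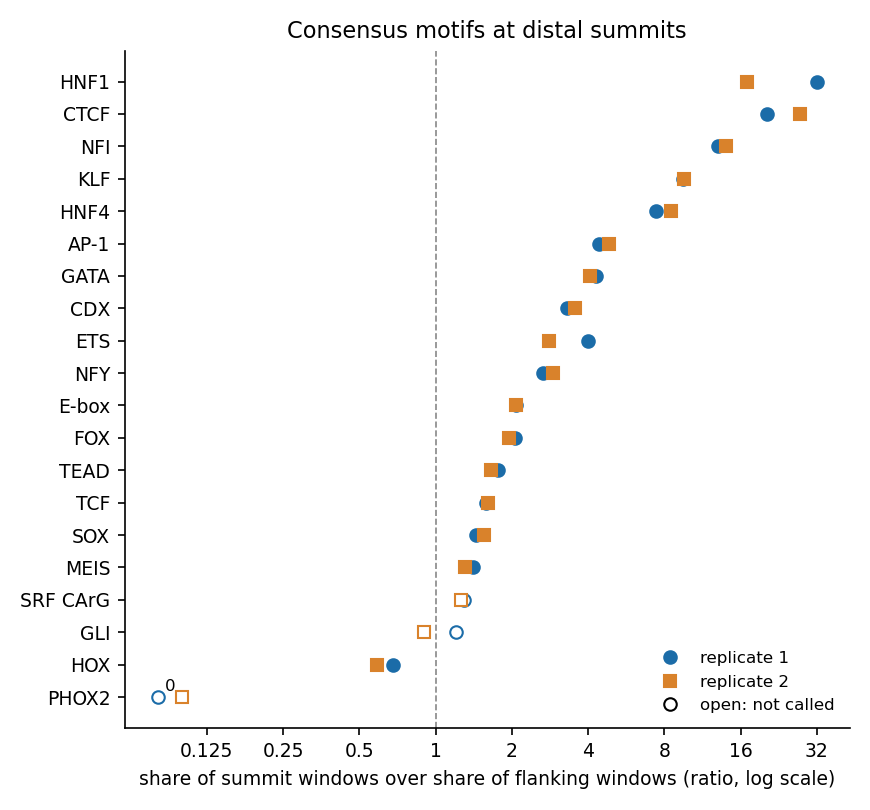
Share of distal summits with each consensus motif over the share in flanking windows (horizontal axis, ratio, log scale), in replicate 1 (circles) and replicate 2 (squares), with motifs not called left open. A ratio of 0 is drawn at the left edge and marked 0. HNF1 and CTCF lie highest, at mean ratios of 24.5 and 23.9.

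No motif passed the test between distal regions near epithelial genes and those near mesenchymal and smooth muscle genes. Fisher's exact test with Benjamini-Hochberg adjustment passed for 0 of 20 motifs, and 1 motif, CArG, had an unadjusted p under 0.05 in both replicates. CDX sites were at 5.76% ± 0.130 of the epithelial regions and 0.926% ± 1.31 of the mesenchymal ones (larger exact adjusted p = 1.00). CArG sites were at 0.258% ± 0.364 and 4.95% ± 0.854 (exact adjusted p = 0.667). The mesenchymal side had 54 regions in replicate 1 and 46 in replicate 2, against 194 and 205, which limits what could be detected.

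The last question was whether the pools differed near genes of a cell type. Of the distal regions, 73.7% in replicate 1 and 73.1% in replicate 2 were found in the other replicate. Regions near epithelial regulators were found more often, at 87.2% ± 3.65 against 73.6% near other genes. Fisher's exact test passed in replicate 1 (adjusted p = 0.00639) and not in replicate 2 (adjusted p = 0.302). That call ended with looser and with stricter lists, and when each of a pair of regions had to be covered by at least 50%. Gut mesenchyme was called with looser lists and erythroid with stricter ones, each in at least 1 replicate, with no direction recorded. In the main setting no other list passed in either replicate. Unadjusted, 2 lists in replicate 1 and 3 in replicate 2 had an exact p under 0.05. Erythroid genes had 13 distal regions in replicate 1 and 5 in replicate 2, and in replicate 1 the exact p of 0.00798 for a lower share found became 0.108 after adjustment.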

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

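No test of this part was chosen only after its result was seen. Ranked lists were used in no comparison above, and they hold a signal that the thresholded lists lack. On the main chromosomes, 66 regions of replicate 1 and 67 of replicate 2 reached the score of the threshold in the ranked list and were missing from the thresholded list. Their median −log10 p was 128 in replicate 1 and 88.0 in replicate 2, against 52.6 and 53.8 in the regions kept. The most extreme in replicate 1 spanned 24611586 to 24616160 on chromosome 1, with a −log10 p of 4146 and a signal value of only 3.26.

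Mitochondrial DNA copied into the nuclear genome was argued against for the set. A mean of 1.504% of the missing regions matched the mitochondrial chromosome over at least 100 bp. The chromosome 1 region is the exception, with a match of 4575 bp. Among 500 kept regions drawn at random per replicate, 0.00% matched. Other kept regions did match, such as those nearest to Abcb11, G6pd2 and Gm5426 in the conservative list. Sequence present in several copies stays open as part of the cause. A mean of 36.9% of the missing regions occurred at 2 or more further places of the assembly, against 0.9% of the kept regions drawn. That is below the 50% that was asked of it as the main cause. Their removal through the further file that is not described was not tested, and the design gives no biological explanation to test.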

How the results depend on the processing

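All alternatives were chosen before the data were examined. No call of a gene list by distal regions turned in direction, and the cause of the changes below was not tested. Peaks as listed, not merged and with an interval repeated for each summit, averaged 74974 per replicate. The looser lists had 73891 regions, against 29614. In the conservative pooled list there were 40438 regions, and its calls come from a single list, without the rule of both replicates. Replicate overlap (83.1%) was 80.1% with at least 50% of both regions, 76.5% with summits within 100 bp, 79.5% with looser and 87.0% with stricter lists. Rank agreement was 0.937 by the p column. The promoter share (48.4%) was 28.0% with looser, 65.9% with stricter lists, 39.8% in the conservative pooled list, and 45.1% and 54.0% with windows of 500 and 2500 bp. Without 1 replicate it was 48.38% to 48.42%.

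Calls of lists by promoters numbered 17 in the main setting and 10 with looser lists, 8 of them shared. Without 1 replicate they numbered 17 to 19. With looser lists the share of accessible promoters turned above other genes for enteric nervous system (83.3%), kidney (71.9%) and Hox groups 5 to 9 (73.3%) and 10 to 13 (75.0%), none of them called. With stricter lists that of junction and keratin genes (36.4%) turned below them, not called. The calls of epithelial regulators and of stem cell and Wnt target genes also ended there, while 19 of the 20 calls made were lower, among them absorptive enterocyte, secretory, gut mesenchyme, endothelium, mesothelium, pancreas and Hox groups 1 to 4, which had no call before. In the looser and the conservative pooled lists gut mesenchyme and smooth muscle were called as higher. By construction, stricter lists lose promoters of low signal.

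Calls by distal regions numbered 2 to 4 over the alternatives, against 3, and 3 to 4 without 1 replicate. The list gained under 4 of them, the looser, conservative and unmatched settings and without replicate 1, was stem cell and Wnt target genes. Gut lists minus other lists stayed positive and not called, with a log2 difference of 0.16 with stricter lists (1 list without a region left out), 0.39 to 0.49 without 1 replicate, and permutation p of 0.0602 to 0.677 over the alternatives. Motif calls numbered 15 to 19 against 17, and 17 to 18 without 1 replicate. CArG was called in 3 settings (looser lists, conservative pooled list, reversed consensus) and PHOX2 in 4 (looser lists, conservative pooled list, without replicate 1, window of 100 bp). With the reversed consensus ETS (0.888) and HOX (1.13) turned in direction. No fold could be computed for 3 motifs with the reversed consensus (HNF1, CTCF, NFI) and 2 with the window of 25 bp (HNF1, NFI), where the background share was 0. No motif told epithelial from mesenchymal regions under any alternative (0 calls, also without 1 replicate). The list whose regions were found more often in the other replicate was lost with at least 50% of both regions (0 lists). That list was also lost with looser lists, which called gut mesenchyme, and with stricter lists, which called erythroid. The direction of these 2 calls was not recorded, and each needed 1 replicate only. In the main setting the erythroid share found was lower in replicate 1, at 38.5% against 73.7% near other genes. Over single lists by promoters or distal regions and single motifs, 695 values stayed on their side of the threshold, called or not, 24 gained a call, 21 lost it and 7 lost it and turned. No paired analysis was possible because there is only one group. Unknown depth limits every list: a missing region is not shown to be closed.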

Other observations

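Of the tests behind this part, the McNemar test of erythroid promoters and that of other promoters open in 1 replicate were chosen only after the result was seen.

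Promoter signal values, which were not tested between gene lists, were not highest in the 3 epithelial and stem cell lists called as higher by promoter counts. Among members open in both replicates, the median was 9.97 ± 0.223 (SD, n = 2) for all protein-coding genes and 9.64 ± 0.0104 for ribosomal protein genes. It was 7.34 ± 0.483 for epithelial regulators, 7.30 ± 0.431 for stem cell and Wnt target genes and 6.73 ± 0.231 for junction and keratin genes. Lists called as lower rested on few genes and lay on both sides of these values, with stomach (9.39 ± 0.508, 2 genes), heart (9.36 ± 0.507, 3 genes), lung (8.68 ± 0.00906, 3 genes), epidermis (7.96 ± 1.06, 2 genes), kidney and urogenital ridge (7.87 ± 0.187, 4 genes) and enteric nervous system (7.68 ± 0.559, 6 genes) above them, skeletal muscle (6.92 ± 0.128, 4 genes) and leukocyte (6.74 ± 0.157, 3 genes) among them, and forebrain (6.53 ± 0.170, 4 genes) and liver (5.77 ± 0.196, 3 genes) below. Over the lists with such a member the values ran from 5.398 ± 0.00608 (Hox groups 5 to 9, 2 genes) to 10.00 ± 0.177 (germ line, 1 gene).

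Erythroid promoters open in 1 replicate only numbered 9 in replicate 1 and 0 in replicate 2, a difference between single libraries that did not pass after adjustment (exact McNemar adjusted p = 0.105). More regions called in replicate 1 was argued against, since among other genes 389 promoters were open in replicate 1 only and 464 in replicate 2 only, a ratio of 0.838. That this ratio is below 1 follows from the totals above, 13295 and 13361 accessible promoters, so it is no separate test. A larger share of red blood cell precursors in replicate 1 is a candidate explanation for the erythroid counts, since the GATA motif, which the erythroid factor Gata1 binds, was at 6.98% of the 4012 distal regions found in replicate 1 only and 3.71% of the 4126 found in replicate 2 only (Fisher's exact test, p = 5.09e-11). It was the only 1 of 20 motifs to pass after adjustment, but Gata4 and Gata6 of the epithelium bind the same motif, so a difference in epithelium stays open. In the looser list of replicate 2, 7 of the 9 promoters were accessible.

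An excess of distal regions was called near genes of 3 epithelial lists and not for gut mesenchyme or smooth muscle, but no test compared the lists, an excess near 2-fold can be missed, and secretory genes (ratio 1.08) were not called either. With the looser lists the ratio of gut mesenchyme was 1.20 ± 0.257 (permutation adjusted p = 0.997), and that of smooth muscle was 2.13 ± 0.209 (permutation adjusted p = 0.0605), and with an assignment limit of 500000 bp the ratio of gut mesenchyme was 1.19 ± 0.0965 (permutation adjusted p = 1.00). In both settings 1 replicate exceeded the bound set beforehand for arguing against the threshold or the limit, and neither setting gave a call, so their part cannot be told apart. If the pools held more epithelial nuclei, distal regions near epithelial genes might have higher signal values. Their medians exceeded those near mesenchymal genes by 0.431 and 0.154 in the replicates, a mean of 0.292, with permutation p of 0.291 and 0.705, so this stays open too.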
